A study of Homo sapiens with 36 samples.

How the data were processed

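Polyadenylated RNA was sequenced from 36 libraries of prostate cancer cells, 3 in each of 12 groups. LNCaP is an androgen-dependent line from a lymph node metastasis, and 42D is an enzalutamide-resistant line derived from LNCaP. LNCaP was sampled as 4 lines, named NT3, sgT33-5, sgT33-5_MC_C2 and sgT33-5_MC_F2, and 42D as NT3 and sgT33-5. The labels do not expand these names. From the title of the series, sgT33-5 was read as a guide RNA against TRIM33 and NT3 as the non-targeting control, and the last 2 LNCaP names are shortened here to C2 and F2. Each line received DMSO or 5 nM of the synthetic androgen R1881 for 6 h after culture in hormone-stripped serum. The labels give triplicates with replicate numbers and do not say whether the replicates were separate cultures, so p-values here measure the spread between these samples.

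Per the labels, the authors trimmed reads with cutadapt, aligned them to GRCh38 (hg38) with HISAT2 2.1.0 and deposited a table of raw gene counts for all libraries. The values are whole numbers, and no scaling or correction before deposit was found in them. The table holds 61806 entries, of which 61805 carry a gene name and the other holds 0 counts. Library totals were 13900744 to 19793268 counts. In 36 pairs of replicates, the chi-square per gene of 1 library against the other was 2.73 to 26.6, where counting error alone would give about 1. On average over genes, the spread between libraries therefore exceeded counting error. The part that depth plays for genes with low counts was not tested. Genes of the mitochondrial chromosome took 2.14% to 6.66% of the counts in LNCaP and 2.94% to 4.59% in 42D.

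Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, expression filter by group, robust quasi-likelihood F test, 2-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 24 LNCaP libraries were fitted together (15519 genes), the 12 libraries of 42D together (15403 genes), and all 36 for comparisons between the cell lines (16564 genes). Within each line R1881 was compared with DMSO. Each sgT33-5 line was compared with NT3 at either treatment, and an interaction term tested whether the R1881 response differed from that of NT3. Between cell lines the tests were 42D against LNCaP in NT3 with DMSO, the difference in the NT3 response, and the difference in the guide effect with R1881. Log2 fold changes come with a standard error (SE) taken from the fold change and the F statistic. Levels are in CPM (counts scaled to the TMM-adjusted library total) with the SD over 3 libraries.

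Before the data were examined, 17 gene lists were fixed from general knowledge: androgen response, androgen repressed, androgen signalling cofactors, H2B ubiquitination machinery, TGF-beta and SMAD targets, cholesterol synthesis, cell cycle, unfolded protein response, p53 targets, interferon response, hypoxia and glycolysis, neuroendocrine and lineage plasticity, luminal prostate, basal prostate, mesenchymal, leukocyte, and Wnt targets. A further 2 lists per cell line held the genes that R1881 induced or repressed at least 2-fold in NT3 cells of the other cell line, so that no list was chosen on the libraries it was tested in. In LNCaP, 354 of 440 induced and 208 of 275 repressed genes passed the expression filter and were tested. In 42D these were 237 of 270 and 88 of 112. Each list was tested against all other genes with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation of 0.01), again with an estimated correlation, and with fry. The 372 list tests formed 1 family for adjustment.

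Genes named in the text follow a rule fixed at the same time. It takes a panel of 18 genes around TRIM33 and androgen signalling, the 10 highest and 10 lowest called changes per listed comparison (mean of at least 5 CPM, no overlap between the libraries compared), the same for genes called in 1 direction in all 3 LNCaP guide lines, and from each list the 2 called members with the largest change in each direction. Some genes that the rule names, and a test that used 1 of them, are not reported here. A gene outside the rule is marked as chosen after its values were seen. KLK2 and KLK3, like UGT2B15 and UGT2B17, are close paralogs, and CCDC141 overlaps the end of TTN, so reads of these genes may be shared.

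Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of only the libraries compared, a 2-fold minimum, the replicate number as a block, an estimated correlation, and each library left out in turn. Leaving out the 2 LNCaP libraries of lowest mitochondrial share and leaving out mitochondrial genes were added after the data were seen. Whether the replicate numbers pair the libraries was checked before any blocked fit was compared. Every library correlated best with those of its own number (24 of 24 in LNCaP, 12 of 12 in 42D), with a median correlation of 0.155 against -0.0763 for other numbers in LNCaP. Every pair passed 0.1 in 6 comparisons, which count as paired from the data alone, since the labels do not say what a number shares. These are the R1881 response in F2 and in both 42D lines, sgT33-5 against NT3 in LNCaP with R1881, F2 against NT3 with DMSO, and sgT33-5 against NT3 in 42D with R1881. Counts were also compared with those from other splits of the libraries.

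The procedure was tested on simulated counts with known changes added. For sgT33-5 against NT3 in LNCaP with R1881, edgeR called 65.7% of genes changed 1.5-fold, 92.5% changed 2-fold and 97% changed 4-fold, with 9 false calls among 179. For the interaction these shares were 46.3%, 85.1% and 95.5%. In 42D with R1881 they were 71.6%, 85.1% and 98.5%. Of 100 lists drawn at random, camera called 0 and fry called 4 at an unadjusted p under 0.05. The simulated genes varied independently, so these numbers do not cover lists whose genes move together.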

Results

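RNA sequencing of 36 libraries measured gene expression in 12 groups of 3 (LNCaP NT3, sgT33-5, C2 and F2, and 42D NT3 and sgT33-5, each with DMSO or R1881), at 13900744 to 19793268 counts per library. From its title, the series asks whether loss of TRIM33, a chromatin-bound E3 ubiquitin ligase, changes androgen-driven transcription. Log2 fold changes are given with their SE in brackets, for 3 libraries against 3, and positions are on GRCh38. In LNCaP, 2 libraries stood apart in their mitochondrial share, with 2.14% in sgT33-5 with DMSO, replicate 3, and 2.4% in sgT33-5 with R1881, replicate 1, against 4.16% to 6.66% in the other LNCaP libraries. Both belong to the sgT33-5 line, so total counts, list calls and calls of named genes of that line that change without them are marked. Counts of list members are given with all libraries. With DMSO, the C2 libraries (4.66% to 5.53%) and F2 libraries (5.14% to 5.67%) also lay below those of NT3 (5.7% to 6.66%).

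TRIM33 (ENSG00000197323, chromosome 1, 114392790 to 114511203) was lower in every guide line than in NT3. In LNCaP with DMSO it stood at 93.4 ± 3.81 CPM (SD, n = 3) in NT3, 47.8 ± 4.82 in sgT33-5, 35.1 ± 1.5 in C2 and 42.3 ± 0.897 in F2. With R1881 the levels were 126.5 ± 3.41, 59.9 ± 6.79, 42.4 ± 3.74 and 58.4 ± 4.83 CPM in the same order. The log2 fold changes against NT3 were -0.96 (0.079) and -1.07 (0.077) in sgT33-5, -1.41 (0.08) and -1.57 (0.078) in C2, and -1.14 (0.079) and -1.12 (0.077) in F2, for DMSO and R1881. In 42D the fall was smaller, from 84.5 ± 4.83 to 57.3 ± 2.33 CPM with DMSO and from 105.3 ± 3.45 to 73.9 ± 1.04 CPM with R1881, which are log2 fold changes of -0.55 (0.052) and -0.52 (0.051). No guide library reached the lowest NT3 library of its cell line and treatment. R1881 raised TRIM33 itself in NT3, by 0.43 (0.075) in LNCaP and 0.34 (0.05) in 42D on the log2 scale. Transcript levels do not measure the TRIM33 protein.

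**Figure D1:**
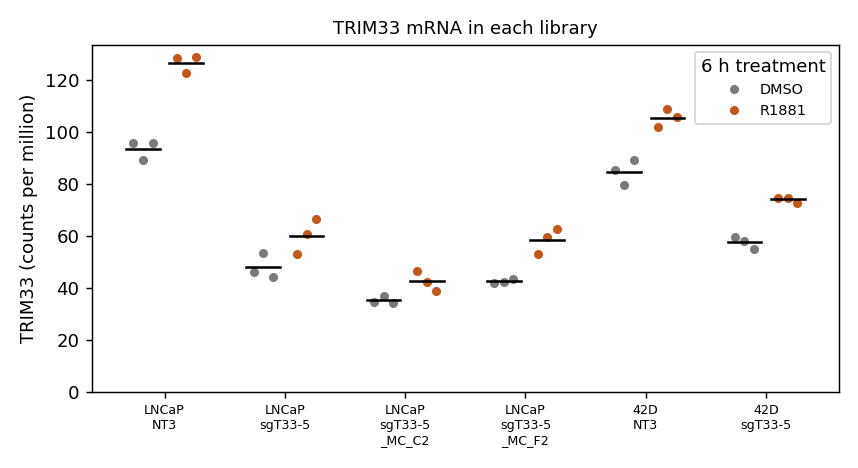
TRIM33 level in CPM (linear axis from 0) in each of the 36 libraries, by line and treatment; points are libraries and bars are group means of 3. Group means in LNCaP run from 35.1 (C2, DMSO) to 126.5 (NT3, R1881), and in 42D from 57.3 (sgT33-5, DMSO) to 105.3 (NT3, R1881).

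In LNCaP NT3 cells, 6 h of R1881 raised genes that were close to silent in hormone-stripped serum. CCDC141 rose from 0.104 to 25.4 CPM, SLC38A4, an amino acid transporter, from 0.091 to 14.5 CPM, and STEAP4, a metalloreductase, from 0.111 to 11.9 CPM. SGK1, a kinase induced by steroids, rose by 5.53 (0.314), the transcription factor MAF by 3.79 (0.207), the serine protease TMPRSS2 by 3.48 (0.143) and the immunophilin FKBP5, a textbook androgen target, by 3.02 (0.09). KLK3, which encodes prostate-specific antigen, rose by 0.99 (0.198) from an already high 1369 CPM. The largest falls were those of the zinc and manganese transporter SLC30A10, by -1.98 (0.203), phospholipase PLD1, by -1.81 (0.115), the bile salt pump ABCB11, by -1.65 (0.282), the opioid receptor OPRK1, by -1.55 (0.196), and the TGF-beta pseudoreceptor BAMBI, by -1.44 (0.122). In all, 2042 genes changed, 1242 upward and 800 downward, and 382 of them at least 2-fold. Of the 99 tested androgen response genes, 75 rose and 0 fell (78 and 1 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 1.43e-51). Of the 15 androgen repressed genes, 5 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.098, and 0.0191 without NT3 with R1881, replicate 2), TMEFF2 against the name of its list, by 1.4 (0.198).

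In 42D NT3 cells the same treatment changed 3901 genes, 2142 upward and 1759 downward. STEAP4 rose by 6.47 (0.275), the ubiquitin-conjugating enzyme gene UBE2QL1 by 6.07 (0.229), SGK1 by 5.42 (0.219), the catenin CTNNA2 by 5.02 (0.104), NDRG1, a stress-response gene, by 4.26 (0.101) and FKBP5 by 3.89 (0.047). The transcription factor FOXQ1 fell by -2.66 (0.182), the myelin gene PMP22 by -2.63 (0.135), the prolactin receptor PRLR by -2.45 (0.162) and the Wnt ligand WNT5A by -2.29 (0.062). Of 99 androgen response genes, 74 rose and 1 fell (77 and 1 adjusted over the list alone; median 0.78, camera adjusted p = 8.64e-37), and of 15 androgen repressed genes 10 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 1.33e-05). Among genes tested in both cell lines, 879 rose in both, 541 fell in both and 14 moved in opposite directions, where independent lists would share 168 and 87.4.

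The cell lines differed widely before treatment. With DMSO, 11279 of 16564 genes differed between 42D and LNCaP NT3 cells, 5760 of them higher in 42D. The neural adhesion gene NCAM1 was higher in 42D by 7.29 (0.199) and TMPRSS2 by 1.09 (0.123), whereas KLK3 was lower by -3.48 (0.2) and the prostein gene SLC45A3 by -2.59 (0.16). The lowest named gene in 42D was USP9Y on the Y chromosome, at 575.2 CPM in LNCaP and 0 CPM in 42D. The Y chromosome genes TXLNGY, DDX3Y, RPS4Y1, KDM5D and EIF1AY were also at 0 CPM in 42D. In LNCaP they stood at 87.1, 74.5, 70.1, 69.4 and 40 CPM. Other chromosomes also held genes with RNA near 0 CPM in 1 cell line only, in either direction. NNT stood at 0 CPM in LNCaP and 49.4 CPM in 42D, and FBLN1 at 0 and 34 CPM. ETV1, an ETS transcription factor, stood at 368.1 CPM in LNCaP and 0.0199 CPM in 42D. Of 11 neuroendocrine and lineage plasticity genes, 9 were higher in 42D and 1 lower (the same adjusted over the list alone; median 1.84, camera adjusted p = 0.000542). Of 41 cell cycle genes, 36 were higher in 42D and 0 lower (the same adjusted over the list alone; camera adjusted p = 5e-06, and adjusted p = 0.644 with an estimated correlation). A test of the difference in the R1881 response called 638 genes, 301 with the higher response in 42D. NDRG1 responded more in 42D by 2.11 (0.249), FKBP5 by 0.84 (0.104) and SLC45A3 by 1.03 (0.205), and TMPRSS2 less, by -1.58 (0.167). WNT5A fell further in 42D, by -2.29 against -0.32 (0.084) in LNCaP, a difference of -1.99 (0.109).

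All 3 LNCaP guide lines responded to R1881. The hormone changed 1936 genes in sgT33-5 (1052 up, 884 down), 879 in C2 (559 up, 320 down) and 1611 in F2 (993 up, 618 down). In F2, whose replicates pair by number, the blocked fit called 2455 (1377 up, 1078 down). FKBP5 rose by 2.61 (0.088) in sgT33-5, 1.77 (0.086) in C2 and 2.62 (0.089) in F2, beside 3.02 in NT3. Of the genes called in NT3, 737 rose and 522 fell in sgT33-5 as well, 517 and 274 in C2, and 884 and 441 in F2, and 0 moved in opposite directions in any of the 3.

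The guide lines were then compared with NT3 at each treatment. With R1881, 238 genes differed from NT3 in 1 direction in all 3 LNCaP guide lines, 56 higher and 182 lower. By pairs, sgT33-5 and C2 shared 103 higher and 294 lower genes, and 6 were called in opposite directions. For sgT33-5 and F2 these numbers were 72, 195 and 21, and for C2 and F2 348, 618 and 134. IGF1R (chromosome 15, 98648539 to 98964530), the receptor for insulin-like growth factor 1, fell from 89.2 ± 3.64 CPM in NT3 to 24.9 ± 5.84 in sgT33-5, 5.62 ± 0.212 in C2 and 24.8 ± 4 in F2 (n = 3 each). KLK3 (chromosome 19, 50854915 to 50860764) fell from 2735 ± 95 CPM to 1034 ± 93.7, 193.5 ± 68.5 and 516.6 ± 75.4, although reads it shares with its paralog KLK2 cannot be told apart. The synaptic vesicle gene SYT4 fell by -1.50, -4.96 and -5.83, the bone morphogenetic protein receptor BMPR1B by -1.28, -4.05 and -1.92, the chondroitin sulfate enzyme CSGALNACT1 by -1.24, -3.42 and -1.54, the androgen-regulated ion channel TRPM8 by -1.06, -1.99 and -1.31, and SLC38A4 by -1.01, -2.38 and -1.15, in sgT33-5, C2 and F2. Higher in all 3 were the secreted phospholipase PLA2G2A (2.0, 2.23 and 1.79, SE 0.071 to 0.072), the CaM kinase inhibitor CAMK2N1 (1.78, 1.79 and 1.85, SE 0.099), the retrotransposon-derived gene PEG10 (0.64, 1.13 and 1.23, SE 0.08), the zinc finger gene ZBTB43 (0.89, 0.57 and 1.23, SE 0.1 to 0.101) and PLD1 (0.77, 1.05 and 0.56). PLA2G2A and CAMK2N1 lie within 1 stretch of chromosome 1, at 19975431 to 19980416 and 20482391 to 20486210.

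With DMSO, 86 genes were called in 1 direction in all 3 lines, 16 higher and 70 lower. By pairs, sgT33-5 and C2 shared 45 higher and 116 lower genes, and 3 were opposite. For sgT33-5 and F2 these numbers were 24, 79 and 26, and for C2 and F2 480, 472 and 125. IGF1R fell by -1.64 (0.2), -3.43 (0.249) and -1.77, KLK3 by -1.51 (0.202), -4.48 (0.231) and -2.65, the Notch ligand JAG1 by -1.12 (0.148), -1.22 (0.148) and -0.99, and the antiproliferative gene BTG1 by -0.71 (0.096), -1.56 (0.099) and -1.15, its call in sgT33-5 ending with only the libraries compared (adjusted p = 0.0617). PLA2G2A rose by 1.93 (0.07), 2.08 (0.07) and 1.77, and CAMK2N1 by 1.52 (0.098), 1.49 (0.098) and 1.56. Independent lists would share 0.602 genes up and 1.03 down with DMSO, and 0.909 and 3.09 with R1881. All 3 comparisons use the same 3 NT3 libraries, and part of the overlap may come from them. The names of all 3 lines also carry the same guide, sgT33-5, and the labels do not say whether the lines share an origin. The overlap therefore cannot separate the loss of TRIM33 from anything else that these lines share. In 20 simulated datasets of unchanged groups against shared controls the highest overlap was 0. Those datasets held only the spread between libraries, so they do not test an NT3 line that itself differs from the guide lines. The number shared with R1881 was 111 without NT3 with R1881, replicate 1, 120 without replicate 2, 116 without sgT33-5 with R1881, replicate 1, 148 without replicate 2, 113 without the 2 libraries of low mitochondrial share, and 85 with only the libraries compared. With DMSO it was 55 without NT3 with DMSO, replicate 1, and 57 without sgT33-5 with DMSO, replicate 2.

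**Figure D2:**
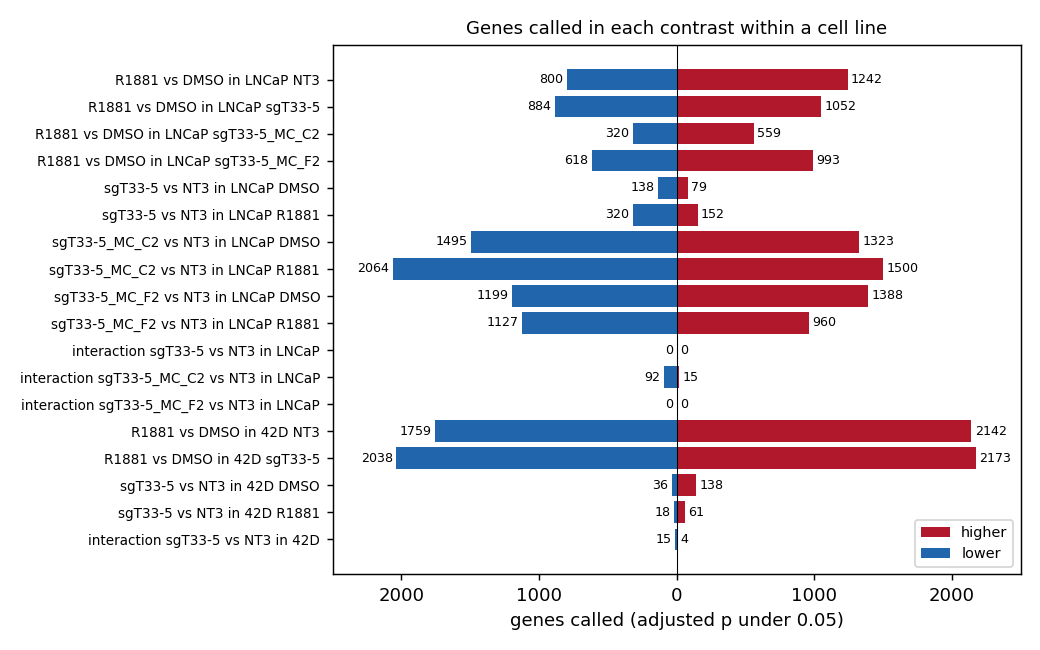
Number of genes called higher (right) and lower (left) in each comparison within a cell line (edgeR, adjusted p under 0.05; bars start at 0). Among guide lines against NT3, C2 with R1881 has 1500 higher and 2064 lower genes, and 42D sgT33-5 with R1881 has 61 and 18.

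In the sgT33-5 line itself, 472 genes differed from NT3 with R1881, 152 higher and 320 lower, and 217 with DMSO, 79 higher and 138 lower, and 40 higher and 88 lower genes were common to both treatments. Among androgen targets with R1881, CAMKK2, a kinase of energy metabolism, fell by -0.34 (0.066) and KLK3 by -1.40 (0.2), and both calls held whichever library was left out, while that of CAMKK2 ended with only the libraries compared (adjusted p = 0.0661). TMPRSS2 fell by -0.62 (0.128), SLC45A3 by -0.58 (0.123), NDRG1 by -0.89 (0.183), FKBP5 by -0.32 (0.081), the elongation factor ELL2 by -0.29 (0.078) and the drug efflux pump ABCC4 by -0.39 (0.094). All 6 of these calls ended without sgT33-5 with R1881, replicate 1 (adjusted p = 0.0685, 0.0903, 0.0802, 0.196, 0.222 and 0.163, in this order), without NT3 with R1881, replicate 2 (0.0643, 0.0799, 0.0692, 0.137, 0.202 and 0.133), and without the 2 libraries of low mitochondrial share (0.0822, 0.0955, 0.0955, 0.216, 0.176 and 0.127). Without NT3 with R1881, replicate 1, those of TMPRSS2 (0.0532), FKBP5 (0.0821), ELL2 (0.127) and ABCC4 (0.0618) ended, and without sgT33-5 with R1881, replicate 2, those of FKBP5 (0.109), ELL2 (0.109) and ABCC4 (0.0771). With only the libraries compared, those of NDRG1 (0.098), FKBP5 (0.136), ELL2 (0.0999) and ABCC4 (0.0708) ended. The pioneer factor FOXA1 was at -0.02 (0.078; adjusted p = 0.928). The count with R1881 was 201 without NT3 with R1881, replicate 1, 223 without replicate 2, 198 without sgT33-5 with R1881, replicate 1, 275 without replicate 2, 188 without the 2 libraries of low mitochondrial share, 194 with only the libraries compared, and 1264 (452 up, 812 down) in the blocked fit, whose replicates pair by number. With DMSO it was 119 without NT3 with DMSO, replicate 1, 106 and 118 without sgT33-5 with DMSO, replicates 2 and 3, and 128 without the 2 libraries of low mitochondrial share.

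C2 and F2 differed from NT3 in many more genes. C2 had 2818 calls with DMSO (1323 up, 1495 down) and 3564 with R1881 (1500 up, 2064 down). F2 had 2587 (1388 up, 1199 down) and 2087 (960 up, 1127 down). With R1881, TMPRSS2 fell in C2 by -2.09 (0.133), NDRG1 by -2.31 (0.195), SLC45A3 by -1.82 (0.127), ELL2 by -1.54 (0.081), ABCC4 by -1.26 (0.096), FKBP5 by -1.14 (0.083) and CAMKK2 by -1.13 (0.067). In F2, NDRG1 fell by -0.94 (0.182), SLC45A3 by -0.62 (0.123), the TGF-beta feedback gene PMEPA1 by -0.60 (0.122), FKBP5 by -0.54 (0.082) and CAMKK2 by -0.34 (0.066), while TMPRSS2 was at -0.19 (adjusted p = 0.38). KLK2 was higher in F2 at both treatments, by 1.56 (0.341) with DMSO, opposite to its paralog KLK3. Its call with R1881 ended without the filter on low counts (1.089, adjusted p = 0.0619). The C2 count with DMSO was 1841 without C2 with DMSO, replicate 1. The F2 count with DMSO was 1524 without NT3 with DMSO, replicate 1, and 3926 (2100 up, 1826 down) in the blocked fit, and with R1881 it was 1178 with only the libraries compared.

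**Figure D3:**
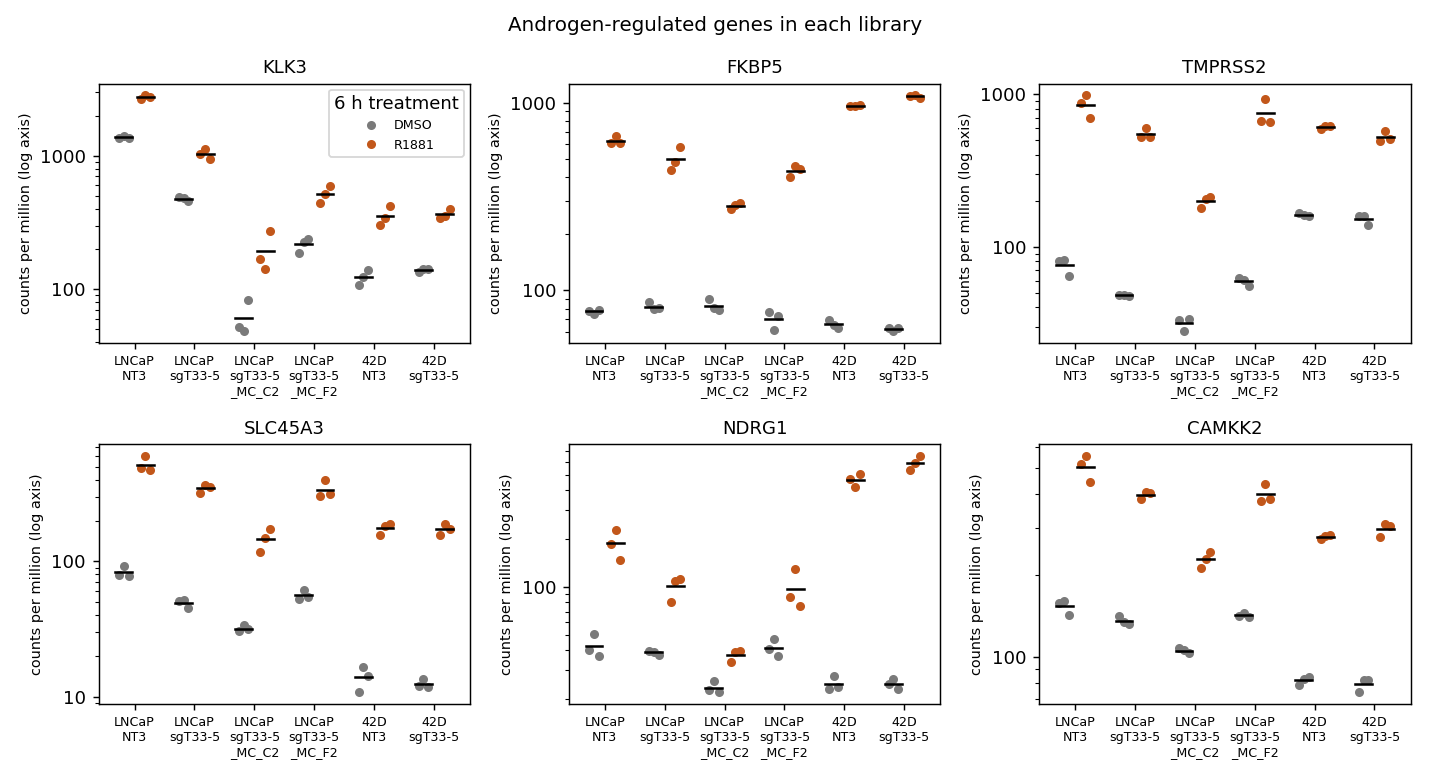
CPM of KLK3, FKBP5, TMPRSS2, SLC45A3, NDRG1 and CAMKK2 in each library (log axes), by line and treatment; points are libraries and bars are group means of 3. KLK3 with R1881 averages 2735 in LNCaP NT3, 1034 in sgT33-5, 193.5 in C2 and 516.6 in F2, and 355.7 and 365.9 in 42D NT3 and sgT33-5.

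The androgen-driven genes moved as groups. Of the 99 androgen response genes with R1881, 36 were lower and 0 higher than in NT3 in sgT33-5 (51 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 1.65e-18). In C2, 72 were lower and 3 higher (74 and 5 adjusted over the list alone; median -0.54, adjusted p = 1.23e-28), and in F2 33 and 6 (47 and 7 adjusted over the list alone; median -0.18, adjusted p = 4.16e-07, and adjusted p = 0.23 with an estimated correlation). The genes that R1881 induced in 42D NT3 cells were chosen without the LNCaP libraries, and the 354 that passed the LNCaP expression filter were tested. They gave the same direction with R1881. In sgT33-5 79 of them were lower and 2 higher (140 and 6 adjusted over the list alone; median -0.27, adjusted p = 2.15e-23), in C2 255 and 6 (277 and 7 adjusted over the list alone; median -0.73, adjusted p = 5.92e-45) and in F2 141 and 10 (170 and 12 adjusted over the list alone; median -0.33, adjusted p = 1.49e-17). These 3 calls held with an estimated correlation (adjusted p = 0.017, 0.00102 and 0.0403), and without the 2 libraries of low mitochondrial share the sgT33-5 median was -0.21. With DMSO the shifts were smaller, with list medians of -0.111 (-0.072 without sgT33-5 with DMSO, replicate 2), -0.165 and -0.081 and adjusted p = 0.000258, 7.91e-08 and 0.0292. They were lost with an estimated correlation (adjusted p = 0.525, 0.254 and 0.685), and the F2 call also ended without NT3 with DMSO, replicate 1 (adjusted p = 0.0708), or F2 with DMSO, replicate 3 (adjusted p = 0.0681). Androgen response genes with DMSO were lower in C2 (35 lower, 7 higher; 40 and 9 adjusted over the list alone; median -0.20, adjusted p = 5.65e-09, and adjusted p = 0.147 with an estimated correlation), at a median of -0.025 in sgT33-5 (6 lower, 0 higher; adjusted p = 0.0567) and at -0.06 in F2 (13 lower, 11 higher; adjusted p = 0.287). The sgT33-5 value was called without sgT33-5 with DMSO, replicate 3 (-0.047, adjusted p = 0.00167). The 208 genes that R1881 repressed in 42D were higher with R1881 in C2 (57 higher, 21 lower; 61 and 21 adjusted over the list alone; median 0.26, adjusted p = 4.29e-05, and adjusted p = 0.19 with an estimated correlation). They were not called in sgT33-5 (median 0.06, adjusted p = 0.0636) or F2 (median 0.11, mean -0.09, adjusted p = 0.548). Leaving out NT3 with R1881, replicate 1 (0.089, adjusted p = 0.0371), or sgT33-5 with R1881, replicate 3 (0.101, adjusted p = 0.00812), made them a call in sgT33-5. Of the 452 genes called in sgT33-5 with R1881 and tested in both cell lines, 199 moved opposite to the R1881 response of 42D NT3 cells and 39 with it (7 up, 32 down), where independent lists would share 20.3 and 34.8.

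**Figure D4:**
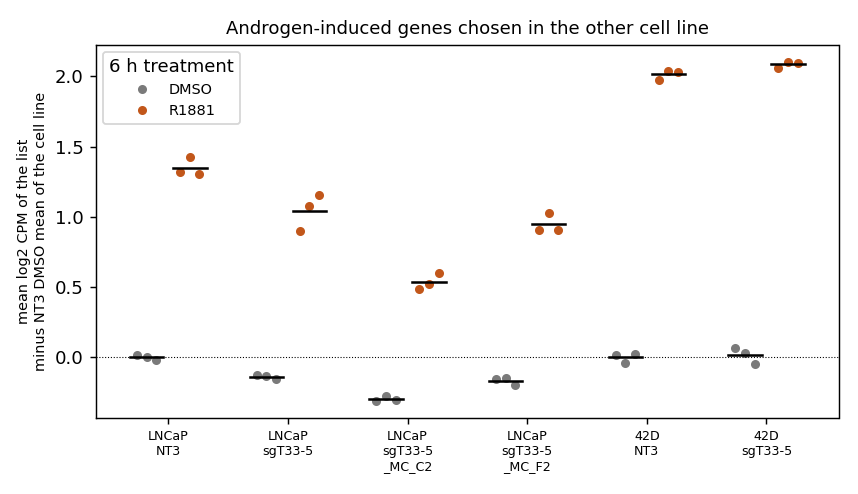
Mean log2 CPM of the genes induced by R1881 in the other cell line (354 genes in LNCaP, 237 in 42D), minus the mean of NT3 with DMSO of the same cell line, in each library; points are libraries and bars are group means of 3. Against NT3 with R1881 the mean changed by -0.307 in sgT33-5, -0.813 in C2 and -0.404 in F2 of LNCaP, and by 0.071 in 42D sgT33-5.

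Whether the R1881 response itself differed was tested by an interaction term. C2 had 107 such genes, 15 higher and 92 lower, among them FKBP5 at -1.25 (0.12), NDRG1 at -1.46 (0.286), ELL2 at -0.68 (0.123), CAMKK2 at -0.59 (0.095) and GRHL2, an epithelial transcription factor, at -0.69 (0.115). The NDRG1 call ended without NT3 with DMSO, replicates 1 (adjusted p = 0.0593) and 3 (0.066), NT3 with R1881, replicate 2 (0.0502), C2 with DMSO, replicate 2 (0.08), or C2 with R1881, replicate 1 (0.0779). In sgT33-5 and F2, edgeR called 0 genes, with 1206 and 454 at an unadjusted p under 0.05 where 776 would come from chance, and DESeq2 called 0 and 4, with 1107 and 413 under 0.05. With the replicate block edgeR called 22 and 17, and without the filter on low counts 26 and 19. Genes called in 1 direction in all 3 lines numbered 0 by edgeR or DESeq2, 2 with the replicate block and 2 without the filter. The induced list responded less in each line, with interaction medians of -0.165 (adjusted p = 1.87e-08), -0.394 (1.61e-57) and -0.161 (5.64e-19) in sgT33-5, C2 and F2. In C2 and F2 the calls held with an estimated correlation (adjusted p = 0.000332 and 0.0335), and in sgT33-5 adjusted p = 0.222 with an estimated correlation. The repressed list from 42D also responded less in C2, at 0.32 (adjusted p = 3.19e-23), and in F2, at 0.15 (9.51e-09), and both held with an estimated correlation (adjusted p = 0.00102 and 0.0448). The mean of this list began lower than in NT3 with DMSO, by -0.127 (0.033) in C2 and -0.207 (0.05) in F2. With R1881 it differed from NT3 by 0.207 (0.053) in C2 and -0.033 (0.044) in F2. By list means the smaller response in F2 thus lay in the level with DMSO. List medians did not place it there alone. They differed from NT3 in F2 by -0.085 with DMSO and by 0.108 with R1881, neither of them called with all libraries. In sgT33-5 the repressed list was not called, at 0.07 (adjusted p = 0.098). It was called without NT3 with DMSO, replicate 3 (0.094, adjusted p = 0.0245), NT3 with R1881, replicate 1 (0.095, adjusted p = 0.0459), or sgT33-5 with R1881, replicate 3 (0.087, adjusted p = 0.0179). The androgen response list was at -0.22 in C2 (adjusted p = 5.43e-29), -0.14 in sgT33-5 (9.48e-10) and -0.065 in F2 (7.75e-09), with adjusted p = 0.0037, 0.123 and 0.151 with an estimated correlation. The F2 median was -0.098 without F2 with DMSO, replicate 2, and -0.106 without F2 with R1881, replicate 2. The C2 count was 70 without NT3 with R1881, replicate 2, 69 and 70 without C2 with DMSO, replicates 1 and 2, and 64 without C2 with R1881, replicate 1. It was 191 without the filter and 326 with the replicate block. The F2 count was 1 without NT3 with DMSO, replicate 2, and 3 without F2 with R1881, replicate 2.

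In 42D, the sgT33-5 line was compared with NT3 in the same way. With DMSO 174 genes changed, 138 higher and 36 lower, and with R1881 79 changed, 61 higher and 18 lower, and 34 higher and 11 lower genes were common to both. NKAIN1 (chromosome 1, 31179745 to 31239887), which encodes a sodium pump partner, rose from 5.61 ± 1.19 to 57.2 ± 10.3 CPM with DMSO and from 5.86 ± 1.78 to 42.5 ± 3.2 with R1881 (n = 3). SERINC2, 1 of its neighbours on chromosome 1 (31409565 to 31434680), rose by 1.92 (0.086) and 1.59 (0.085), the protocadherin PCDH7 by 1.4 (0.123) and 1.5 (0.134), the G protein subunit GNAI1 by 1.37 (0.151) and 1.25 (0.117), and ZBTB43, also higher in all 3 LNCaP guide lines, by 1.13 (0.066) with DMSO. SYT4 fell by -0.83 (0.095) and -0.82 (0.098), the matrix gene TNC by -0.74 (0.122) and -0.78 (0.13), and IGFBP5, an insulin-like growth factor binding protein, by -0.58 (0.067) and -0.52 (0.066). The TNC call with R1881 ended without sgT33-5 with R1881, replicate 1 (adjusted p = 0.0545). These androgen targets did not pass the test with R1881: KLK3 at 0.03 (0.129), TMPRSS2 at -0.23 (0.057; adjusted p = 0.106) and FKBP5 at 0.16 (0.04; adjusted p = 0.113). In the blocked fit of these paired replicates TMPRSS2 (-0.23, adjusted p = 0.0248) and FKBP5 (0.156, adjusted p = 0.00207) were called. Both were also called without the filter (0.000281 and 0.0122), and FKBP5 with DESeq2 (0.00758). NDRG1 did not pass either, but was called as higher with DESeq2 (0.349, adjusted p = 0.0023) and without the filter (0.356, adjusted p = 3.42e-10). Of 99 androgen response genes, 4 were higher with R1881 and 0 lower (16 and 2 adjusted over the list alone; median 0.03, adjusted p = 0.000373, and 0.0336 with an estimated correlation), MAF by 0.74 (0.093) and PMEPA1 by 0.24 (0.045), whose call ended without NT3 with R1881, replicate 3 (adjusted p = 0.0733), or sgT33-5 with R1881, replicate 2 (0.104). With DMSO 1 was higher and 0 lower (median -0.01, mean 0.01, adjusted p = 0.9). The 237 genes induced by R1881 in LNCaP were at a median of 0.04 with R1881 (12 higher, 0 lower; adjusted p = 0.00121, and adjusted p = 0.232 with an estimated correlation). The median was 0.066 without NT3 with R1881, replicate 3, and 0.074 and 0.027 without sgT33-5 with R1881, replicates 1 and 3. The interaction in 42D called 19 genes, 4 higher and 15 lower. DESeq2 called 61, edgeR without the filter 168 and with the replicate block 196. RAB20, a vesicle transport GTPase, was at 1.25 (0.141). Of the 15 lower genes, 7 lie on the mitochondrial chromosome, whose share of the counts was 3.18% and 4.15% in NT3 with DMSO and R1881, and 4.4% and 3.64% in sgT33-5. With the replicate block the calls of MT-CO1, MT-CO3, MT-CYB, MT-ND4, MT-ND4L and MT-ND5 ended (adjusted p = 0.0538 to 0.0835). That of MT-CYB also ended without the filter (0.0649). Without NT3 with R1881, replicate 3, the calls of MT-CYB, MT-ND4L and MT-ND5 ended (0.085 each), and without replicate 2 those of MT-CYB (0.11) and MT-ND4L (0.118). Without sgT33-5 with DMSO, replicate 1, those of MT-CYB (0.0515) and MT-ND5 (0.0583) ended, and without replicate 2 all 3 (0.106, 0.0866 and 0.0641). Without sgT33-5 with R1881, replicate 2, those of MT-CYB (0.064) and MT-ND5 (0.0981) ended. Without mitochondrial genes the interaction count was 5.

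The 42D counts changed with the libraries left out. With DMSO the count was 71 and 77 without NT3 with DMSO, replicates 1 and 3, and 75 and 66 without sgT33-5 with DMSO, replicates 1 and 2. With R1881 it was 48 without NT3 with R1881, replicate 3, and 43 without sgT33-5 with R1881, replicate 2, and 331 (215 up, 116 down) in the blocked fit of these paired replicates. The interaction count was 9 and 42 without NT3 with DMSO, replicates 1 and 2, 92, 5 and 5 without NT3 with R1881, replicates 1, 2 and 3, 8, 8 and 66 without sgT33-5 with DMSO, replicates 1, 2 and 3, and 8 without sgT33-5 with R1881, replicate 2. Fewer libraries also leave fewer degrees of freedom.

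The effect of sgT33-5 with R1881 was compared directly between the cell lines, and 218 genes differed, 191 with the higher value in 42D. KLK3 differed by 1.44 (0.256), IGF1R by 1.69 (0.178), NDRG1 by 1.24 (0.224), ABCC4 by 0.54 (0.127), FKBP5 by 0.49 (0.099) and CAMKK2 by 0.44 (0.087), as did the lineage transcription factor SOX9, by 1.78 (0.316). SOX9 was near the floor in LNCaP, at 2.17 CPM in NT3 and 0.698 in sgT33-5, against 42.9 and 47.8 in 42D. Lower in 42D than in LNCaP were the effects on CAMK2N1, by -1.62 (0.133), PLA2G2A, by -1.43 (0.18), and the nuclear receptor NR2F1, by -1.96 (0.341). NR2F1 was also low in LNCaP, at 1.38 CPM in NT3 and 4.8 in sgT33-5, against 8.74 and 7.765 in 42D. TRIM33 itself differed by 0.57 (0.097). Of the 99 androgen response genes 19 differed upward and 0 downward (56 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 1.26e-23, and 0.00145 with an estimated correlation). The ABCC4 call ended without 42D NT3 with R1881, replicates 1 (adjusted p = 0.0618) and 2 (0.0547), 42D sgT33-5 with R1881, replicates 2 (0.0807) and 3 (0.066), LNCaP NT3 with R1881, replicate 2 (0.0845), or LNCaP sgT33-5 with R1881, replicates 1 (0.102) and 2 (0.0574), and without the 2 libraries of low mitochondrial share (0.446, adjusted p = 0.0655). The NDRG1 call ended with only the libraries compared (1.221, adjusted p = 0.0628). The count was 142 and 135 without LNCaP NT3 with R1881, replicates 1 and 2, 142 without 42D sgT33-5 with R1881, replicate 2, and 140 with only the libraries compared. Genes called in both cell lines with R1881 numbered 5 higher, 4 lower and 7 opposite.

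Among the other fixed lists, the androgen signalling cofactors list, which includes TRIM33, had 3 lower members of 25 in LNCaP sgT33-5 with R1881 (8 adjusted over the list alone; median -0.012, adjusted p = 0.0351, and adjusted p = 0.543 with an estimated correlation), TRIM33 and GRHL2, at -0.38 (0.079), among them. The list call ended without NT3 with R1881, replicate 3 (median 0, adjusted p = 0.0615), sgT33-5 with R1881, replicate 1 (0.001, adjusted p = 0.293), or the 2 libraries of low mitochondrial share (0.001, adjusted p = 0.279). The median was -0.026, -0.047, -0.027 and -0.102 without NT3, replicates 1 and 2, and sgT33-5, replicates 2 and 3. The GRHL2 call ended without sgT33-5 with R1881, replicate 1 (-0.306, adjusted p = 0.067), or those 2 libraries (-0.306, adjusted p = 0.061). The H2B ubiquitination machinery list holds enzymes that place or remove ubiquitin on histone H2B, and partner proteins. Of its 20 tested genes, 0 were called in LNCaP or 42D sgT33-5 at either treatment by edgeR, over all genes or adjusted over the list alone. In C2 with R1881, 6 were lower (6 adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.098). That list was called without C2 with R1881, replicate 1, at -0.062. UBE2E1, a ubiquitin-conjugating enzyme, fell there by -0.31 (0.058). The medians in sgT33-5 were 0.02 and -0.04 in LNCaP (adjusted p = 0.912 and 0.406) and 0.01 and 0.01 in 42D (0.64 and 0.916), for DMSO and R1881. Luminal prostate genes, some of which are androgen targets, were lower in sgT33-5 (4 of 14 at either treatment; 5 with DMSO and 6 with R1881 adjusted over the list alone; adjusted p = 9.8e-05 and 0.000127, and adjusted p = 0.132 and 0.14 with an estimated correlation; without the 2 libraries of low mitochondrial share the member ACP3 lost its call at both treatments, adjusted p = 0.204 and 0.0524) and in C2 with DMSO (8 of 14; 10 adjusted over the list alone; median -0.80, adjusted p = 2.93e-07, and 0.0396 with an estimated correlation), the keratin KRT19 by -1.90 (0.301). Unfolded protein response genes were lower with R1881 in C2 (16 of 26; median -0.26), F2 (12 of 26; median -0.15) and sgT33-5 (3 of 26; median -0.12), with adjusted p = 1.24e-06, 0.000129 and 0.000674, and adjusted p = 0.419, 0.566 and 0.605 with an estimated correlation. Adjusted over the list alone the 3 counts were 16, 14 and 5. The sgT33-5 call ended without NT3 with R1881, replicate 3 (median -0.106), or sgT33-5 with R1881, replicate 2 (-0.082, adjusted p = 0.0788), and without replicate 3 of sgT33-5 the median was -0.19. HSP90B1, 1 of the 3 called members, lost its call without NT3 with R1881, replicates 2 (adjusted p = 0.113) and 3 (0.0761), sgT33-5 with R1881, replicates 1 (0.138) and 2 (0.0933), the 2 libraries of low mitochondrial share (0.148), and with only the libraries compared (0.17). The chaperone HYOU1 fell by -0.63 (0.078) in F2 and CRELD2 by -0.32 (0.064) in sgT33-5. Cholesterol synthesis genes were higher in C2 with DMSO (12 of 24, with 2 lower; 13 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.00666, and adjusted p = 0.525 with an estimated correlation), CYP51A1 by 0.76 (0.184). Wnt targets were higher in C2 with R1881 (5 of 10; 5 adjusted over the list alone; median 0.25, adjusted p = 0.00918, and 0.047 with an estimated correlation), LEF1 by 0.44 (0.1).

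The TGF-beta and SMAD targets had no camera call in any guide line, and with R1881 in sgT33-5 the median was -0.03 and the mean 0.01, with the test downward (adjusted p = 0.386; 0 called by edgeR, 1 lower adjusted over the list alone). Hypoxia and glycolysis genes had no camera call against NT3 in LNCaP sgT33-5 (median 0.04 with R1881, adjusted p = 0.406), nor had mesenchymal genes (median -0.07, adjusted p = 0.391), in which fibronectin, FN1, fell by -0.70 (0.083), nor had basal prostate genes (median -0.11, adjusted p = 0.756), of which 4 were tested. None of the 15 leukocyte genes had enough counts to be tested. Neuroendocrine genes were higher in C2 with DMSO (3 of 7; 3 adjusted over the list alone; adjusted p = 0.00389, and adjusted p = 0.0667 with an estimated correlation), PEG10 by 1.10 (0.079) and enolase ENO2 by 0.62 (0.102). PEG10 was also the 1 called gene of this list in sgT33-5 (adjusted p = 0.501 with DMSO and 0.474 with R1881 for the list). The difference in the effect of sgT33-5 with R1881 between 42D and LNCaP had no camera call in these 5 lists with tested genes (lowest adjusted p = 0.339, neuroendocrine genes), and the 3 LNCaP guide lines were not compared with each other.

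**Figure D5:**
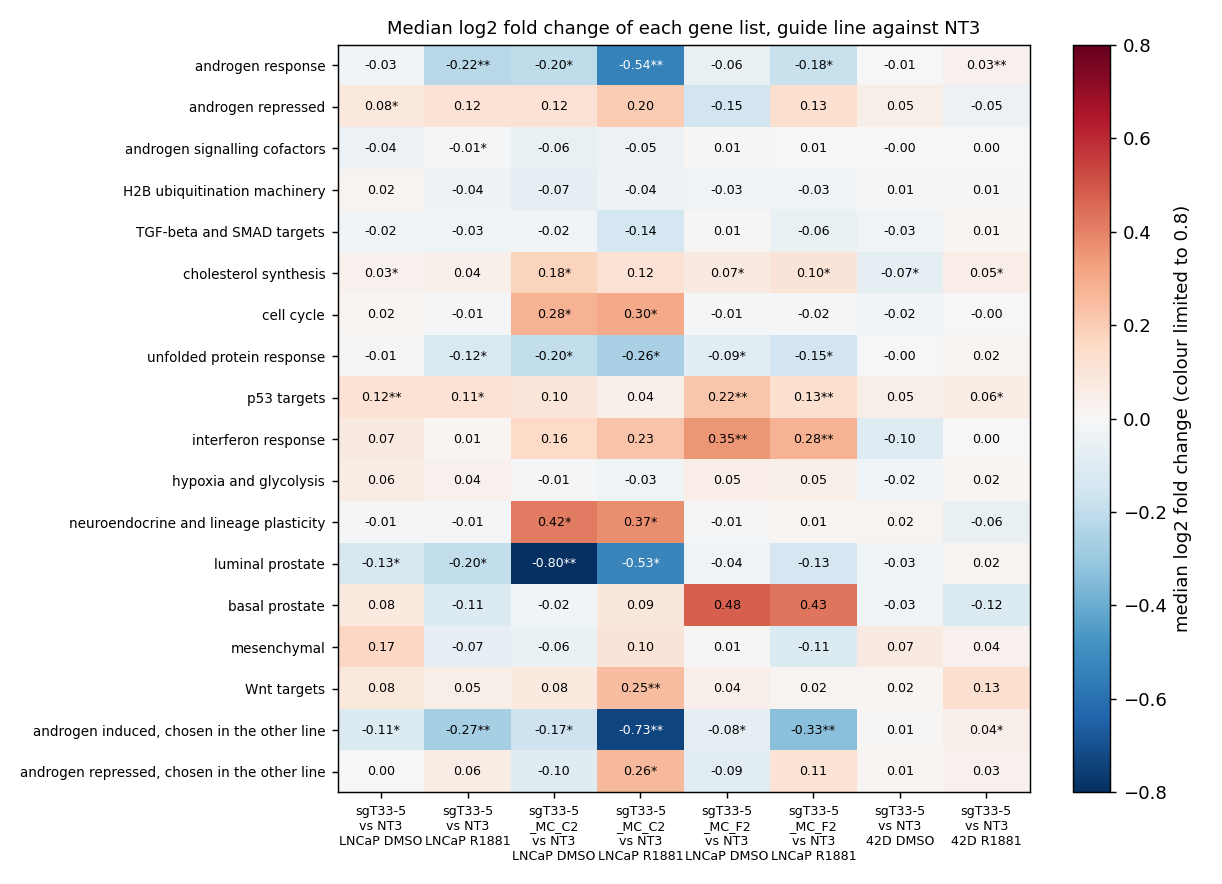
Median log2 fold change of each gene list (vertical axis) for each guide line against NT3 at either treatment (horizontal axis). The lists are the fixed lists with tested genes and those chosen in the other cell line. In each cell, 1 star marks a camera adjusted p under 0.05 and 2 stars that it also holds with an estimated correlation. Androgen response with R1881 is at -0.22 in LNCaP sgT33-5, -0.54 in C2, -0.18 in F2 and 0.03 in 42D sgT33-5.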

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

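The tests of the 2 libraries of low mitochondrial share, of a single NT3 library, of a ceiling, of a difference between lines and of the smaller loss of TRIM33 mRNA were chosen only after the result was seen.

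In LNCaP the genes induced by androgen were lower in sgT33-5 than in NT3 with R1881, at a list median of -0.268. Without the 2 libraries of low mitochondrial share, both of them from the sgT33-5 line, the median was -0.209 (adjusted p = 9.39e-15), which argues against these libraries as the whole cause. Leaving out each NT3 library with R1881 brought the median no closer to 0 than -0.234, which argues against 1 high NT3 library. A loss of androgen-driven transcription after the loss of TRIM33 stays open as a hypothesis, and so does any other difference between 1 NT3 line and 1 guide line, which these libraries cannot separate.

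The R1881 response of androgen-induced genes was smaller in C2 than in NT3, with a list median of -0.394 for the induced genes, 0.318 for the repressed genes and -0.218 for the androgen response genes. A ceiling from higher levels in DMSO would need the induced genes to be higher in C2 before treatment, and their median was -0.165. The repressed genes began lower in C2, with a list mean of -0.127 (SE 0.033) against NT3 with DMSO, so a lower start may account for part of their smaller response and stays open. A difference that arose between lines apart from the guide cannot be told apart from the guide effect, since LNCaP has 1 NT3 line. F2, against the same NT3 libraries, had a median of -0.161 for the induced genes and 0.15 for the repressed genes. The mean of the repressed list in F2 differed from NT3 by -0.207 (SE 0.05) with DMSO and by -0.033 (SE 0.044) with R1881. Its median differed by -0.085 and 0.108.

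The effect of sgT33-5 on androgen response genes with R1881 differed between the cell lines, with a list median of 0.274 for 42D against LNCaP. The list mean changed by 0.049 (SE 0.015) in 42D and by -0.259 (SE 0.053) in LNCaP. TRIM33 fell less in 42D (a ratio of 0.485). In proportion to TRIM33 mRNA the list mean would change by -0.126 there, but no dose response was measured, and a smaller loss of TRIM33 mRNA stays open, for example if the list falls only past some loss. The LNCaP change was 17.3 times the standard error in 42D, so a wide spread in 42D does not account for the difference. TRIM33 protein was not measured and stays open, as does a difference between the cell lines in how they respond to androgen.

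Differences between groups were also found for single genes and counts. The interaction in C2 called 107 genes, with FKBP5 at -1.25, CAMKK2 at -0.59, ELL2 at -0.68 and NDRG1 at -1.46, and that in 42D called 19 genes. The difference in the R1881 response between the cell lines called 638 genes, with TMPRSS2 at -1.58, FKBP5 at 0.84, SLC45A3 at 1.03 and NDRG1 at 2.11, and a median of -0.53 for the androgen repressed list. The difference in the guide effect between the cell lines called 218 genes, with TRIM33 at 0.57, KLK3 at 1.44, FKBP5 at 0.49, CAMKK2 at 0.44, NDRG1 at 1.24 and ABCC4 at 0.54.

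Each count was set against other splits of the same libraries. For comparisons of 3 libraries with 3, the real split was 1 of 10, which is too few for a share under 0.05, and the highest count of another split was 0 or 1, against real counts from 79 to 11279. For genes shared by the 3 LNCaP guide lines, 1 of 25 splits gave as many genes, the real one, at either treatment. The real counts were 86 with DMSO and 238 with R1881, and the highest other was 0 for each. That share is the smallest these splits can give. It argues against counts made by chance among lines with no difference at all. The other splits mix lines too, so they do not test whether the overlap exceeds what separate line effects would share. The splits for interactions and differences mix libraries that differ by line or treatment, and a split that mixes them unevenly can turn that difference into an interaction. They therefore decide nothing about chance for the interaction in C2, where 3 of 25 splits gave as many genes as the real 107 (highest other 1464), that in 42D (2 of 25, real 19, highest other 108), the difference in the R1881 response (4 of 25, real 638, highest other 1900) or the difference in the guide effect (1 of 25, real 218, highest other 164). Splits that call many more genes than the real one point to this structure of the samples. For counts of 0, all 25 splits gave as many, as they must, with highest others of 3 for the interaction in sgT33-5, 510 for F2 and 2 for genes shared by the 3 interactions.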

How the results depend on the processing

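The fits without the 2 LNCaP libraries of low mitochondrial share and without mitochondrial genes were chosen only after the data were seen. For list tests, a change of direction was read from the direction of camera, a choice made after medians near 0 were seen to change sign: of 4626 list medians under an alternative, 475 had another sign, 15 of them with a call in either fit.

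Of 24 counts, 22 stayed within 1.5 times with DESeq2, 23 with RLE factors, 20 with only the libraries compared, 13 without the filter and 6 with the replicate block. Of 7656 values of named genes with 1 library left out, 6987 kept their call, 649 lost it, 20 gained one and 0 reversed. Across the other settings, named genes reversed in 0 of the values. The cell cycle list reversed in the F2 interaction, at 0.075 without F2 with DMSO, replicate 1, and 0.075 without F2 with R1881, replicate 2 (-0.01 with all, and -0.109 to 0.075 over each library left out), and the cause was not tested.

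The replicate block gave 2985, 1398 and 2455 genes for the R1881 response in sgT33-5, C2 and F2, 774 and 1264 for LNCaP sgT33-5 against NT3 (DMSO and R1881), 3926 and 3345 for F2, 665 and 331 for 42D sgT33-5, 22, 326, 17 and 196 for the interactions in sgT33-5, C2, F2 and 42D, 1033 for the response difference, 543 for the guide effect difference, and 251, 615 and 2 for genes shared by the 3 LNCaP lines (DMSO, R1881, interactions). Without the filter, 391 and 743 were called for LNCaP sgT33-5, 438 and 222 for 42D sgT33-5, 26, 191, 19 and 168 for the 4 interactions, 365 for the guide effect difference, and 369 and 2 shared with R1881 and by interactions. Only the libraries compared gave 194 for LNCaP sgT33-5 and 1178 for F2 with R1881, 140 for the guide effect difference and 85 shared with R1881. DESeq2 called 61 for the 42D interaction and 4 for that of F2, and RLE factors 1 for that of F2. Without mitochondrial genes these were 5 and 1. Without the 2 libraries of low mitochondrial share, 128 and 188 were called for LNCaP sgT33-5 and 113 were shared with R1881.

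A minimum of 2-fold left 382, 311, 165 and 270 genes for the R1881 response in LNCaP NT3, sgT33-5, C2 and F2, 715 and 769 in 42D NT3 and sgT33-5, 34 and 60 for LNCaP sgT33-5 against NT3, 467 and 603 for C2, 359 and 357 for F2, 20 and 14 for 42D sgT33-5, 15 and 2 for the C2 and 42D interactions, 3810 for 42D against LNCaP, 130 for the response difference and 39 for the guide effect difference, since fewer genes can pass.

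With an estimated correlation, calls were lost for the induced list in sgT33-5, C2 and F2 with DMSO (-0.111, -0.165, -0.081), in 42D with R1881 (0.043) and in the sgT33-5 interactions of LNCaP (-0.165) and 42D (0.046), for the repressed list in C2 with R1881 (0.258), and for androgen response in C2 with DMSO (-0.201), F2 with R1881 (-0.18), and the interactions of sgT33-5 (-0.14), F2 (-0.065) and 42D (0.04). The induced list lost its 42D interaction call with RLE factors (0.056). Calls were gained for the repressed list in F2 with DMSO without the filter (-0.082), and for androgen response in sgT33-5 with DMSO without the filter (-0.02), with the block (-0.024) and without the 2 libraries (-0.047).

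With 1 library left out, the counts ran from 106 to 170 and 198 to 497 for LNCaP sgT33-5 (DMSO and R1881), 1841 to 2478 for C2 and 1524 to 2343 for F2 with DMSO, 66 to 244 and 43 to 74 for 42D sgT33-5, 64 to 107, 0 to 3 and 5 to 92 for the interactions in C2, F2 and 42D, 135 to 246 for the guide effect difference, and 55 to 88 and 111 to 243 for shared genes. List medians ran from 0.036 to 0.074 (induced, 42D interaction), -0.096 to -0.057 (induced, F2 with DMSO), 0.028 to 0.095 and 0.026 to 0.101 (repressed, sgT33-5 interaction and R1881), -0.116 to -0.049 (repressed, F2 with DMSO), -0.111 to -0.072 (induced, sgT33-5 with DMSO), 0.027 to 0.074 (induced, 42D with R1881), and -0.047 to -0.002, -0.106 to -0.047 and 0.025 to 0.06 (androgen response, sgT33-5 with DMSO and the F2 and 42D interactions). Apart from stated constructions, the causes were not tested. On average over genes the spread between libraries exceeded counting error, and how far depth limits these counts was not tested.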

Other observations

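Interferon response genes were higher in F2 than in NT3, 14 of 32 with DMSO and 13 with R1881, where 2 were lower (19, and 16 and 2, adjusted over the list alone; medians 0.35 and 0.28, adjusted p = 2.48e-08 and 1.15e-06, and 0.000134 and 0.000389 with an estimated correlation). SAMD9, an antiviral gene, rose by 2.25 (0.29) and 1.72 (0.269). p53 targets were higher in F2, 8 of 25 with DMSO and 5 with R1881 (12 and 5 adjusted over the list alone; medians 0.22 and 0.13, adjusted p = 2.93e-06 and 0.000127), PHLDA3 by 0.80 (0.091) and 0.70 (0.094). In sgT33-5, 2 p53 targets were higher at either treatment (5 with DMSO and 2 with R1881 adjusted over the list alone; adjusted p = 1.34e-05 and 0.0015, the latter 0.0818 with an estimated correlation), CCNG1 by 0.31 (0.054) with DMSO. Without the 2 libraries of low mitochondrial share the calls of RPS27L with DMSO (adjusted p = 0.114) and of PHLDA3 (0.256) and PLK3 (0.202) with R1881 ended. With only the libraries compared they ended as well (0.0849, 0.0776 and 0.0895). Of single libraries, RPS27L depended on NT3 with DMSO, replicates 1 (0.123) and 3 (0.145), and sgT33-5 with DMSO, replicates 2 (0.187) and 3 (0.113), PHLDA3 on NT3 with R1881, replicates 1 (0.185) and 2 (0.142), and sgT33-5 with R1881, replicates 1 to 3 (0.266, 0.0549 and 0.0539), and PLK3 on NT3 with R1881, replicates 1 (0.152) and 3 (0.118), and sgT33-5 with R1881, replicates 1 to 3 (0.181, 0.0531 and 0.0586). Cell cycle genes were higher in C2, 13 of 41 with DMSO and 19 with R1881 (19 and 23 adjusted over the list alone; adjusted p = 5.56e-08 and 3.33e-08, and adjusted p = 0.605 for both with an estimated correlation), the replication licensing gene CDT1 by 0.91 (0.138) and 0.79 (0.141).

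In 42D sgT33-5, genes beside NKAIN1 on chromosome 1 moved with it, a stretch chosen after its values were seen. Of 6 tested genes from NKAIN1 to TINAGL1, 5 were higher with DMSO and 4 with R1881, and 0 were lower. ZCCHC17, between NKAIN1 and SERINC2, rose by 0.52 (0.055) and 0.33 (0.054). Copy number and promoter activity were not measured. In LNCaP, PLA2G2A and CAMK2N1, in a separate stretch of chromosome 1, were higher in all 3 guide lines. The neighbours of these genes were not examined as a set.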
